A study of Desmophyllum pertusum with 36 samples.

How the data were processed

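RNA of polyps of the cold-water coral Lophelia pertusa (also named Desmophyllum pertusum) was measured by RNA sequencing. Per the design text and the labels, fragments of 3 genetically distinct colonies, numbered 1, 3 and 4, were held for 4 months at pH 7.6 or pH 7.9, with polyps taken at week 2, week 4.5 and week 8.5. The labels number the time points 1 to 3, and these were matched here to the weeks in the order in which the design text lists them. The design gives 18 libraries, 1 for each colony, pH and week, and each was sequenced in 2 lanes, so that 36 columns of values were read.

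The values are raw counts of reads per transcript, as the authors deposited them, for 75743 transcripts in each of the 36 columns. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and sequenced as single-end reads on an Illumina HiSeq instrument. FastQC, cutadapt 1.15, Trimmomatic 0.36 and DESeq2 are named in the submitters' processing notes, without their order or role. The aligner, the counting program and the transcript set are not given in the sources used here. Reads shared between near-identical transcripts, alleles or isoforms may therefore have been split or dropped in a way that cannot be followed here, and a transcript with no counts in a library can be absent there or carry a sequence that did not match.

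The transcripts are listed by number and the file does not pair them with gene names. The lists of calcification, ion transport, stress, metabolic and other genes fixed before the data were examined could not be matched, and no list was tested. At most 2 transcripts that rose and 2 that fell are named per comparison. The rule for them was fixed before the data were examined: the largest absolute log2 fold changes among transcripts with an adjusted p below 0.05, a mean log2 CPM (counts scaled to a common library size) of at least 1, and a change of the same sign in every pair of libraries that the comparison holds.

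The 2 lanes of a library were summed and counted as 1 library. A chi-square test of the lanes over transcripts with at least 50 counts gave a statistic per degree of freedom of 0.987 to 1.31. Lanes differed, after Benjamini-Hochberg adjustment, in 5 to 13 transcripts in 3 libraries, all of week 2, and in 0 transcripts in the other libraries, where the statistic was 0.987 to 1.04. Library totals ran from 18042191 to 25651213 counts. Of the 75743 transcripts, 56223 passed the filterByExpr filter of edgeR (minimum count 10 and minimum total count 15, by pH and week), and 0.195% of counts lay outside it. Trimmed mean of M values (TMM) factors ran from 0.825 to 1.17.

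Tests were quasi-likelihood F tests in edgeR 4.0.16 under R 4.3.3, fitted to all 18 libraries together, with Benjamini-Hochberg adjustment. A transcript was called at an adjusted p below 0.05. The first model held a mean for each pH and week plus colony as a fixed term, and gave pH over all weeks and at each week, the weeks and the colonies. The second held a mean for each colony and pH plus week, and gave pH within each colony. Differences of pH effects between weeks or colonies were tested with F tests on 2 degrees of freedom. Fold changes are pH 7.6 over pH 7.9, the later week over the earlier, and the colony named first over the other. Standard errors (SE) are the log2 fold change divided by the square root of F. The CPM of single transcripts were computed with TMM-scaled library sizes. The common dispersion was 0.21 in the first model and 0.145 in the second.

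Colony served as replicate block because the labels place fragments of the same colony at both pH. Whether the libraries of a colony deviated together was checked from the correlation, across transcripts, of the deviations of the 2 pH libraries of a colony and week from the means of their groups. It was above 0.1 in 5 of the 9 pairs and lay between -0.405 and 0.746. The 4 other pairs were colonies 1 and 3 at weeks 4.5 and 8.5. Without the replicate block, the count of calls between weeks 4.5 and 2 was 15 in place of 24.

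The 3 weeks of a colony are repeated samples of that colony, and nothing in the labels says whether the fragments stood in separate tanks. The p-values then measure only the spread between these libraries. Comparisons of colonies compare these 3 colonies.

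Libraries were grouped by average linkage on 1 minus Spearman's correlation of log2 CPM (prior count 2) over every other transcript, into 3 sets. The remaining transcripts served to count those with at least 100 counts in one library and 0 in another. The number of sets and the minimum of 100 counts were chosen after the data had been seen. The same holds for the fits with the library set in place of colony, for those without 5 libraries and for those of pH over all weeks without 1 week.

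The procedure was tested on simulated counts for 54900 transcripts with 200 changed. For pH over all weeks it called 33 of 100 transcripts changed 2-fold and 97 of 100 changed 4-fold, with 3 false calls. At single weeks it called 0 to 2 of 100 at 2-fold and 31 to 38 of 100 at 4-fold, and in single colonies it called 0 of 100 at 2-fold and 19 to 35 of 100 at 4-fold. The simulated libraries had no sets and no differences between colonies or weeks. Their spread was estimated from the 18 libraries under the first model, where differences between sets count as spread. The common dispersion was 0.21 there and 0.0944 with the library set in place of colony. These shares are therefore not those for libraries without sets. In single colonies pH was tested with the second model, where the common dispersion of the data was 0.145. The shares for single colonies thus belong to a larger spread than that model found.

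Alternatives were size factors of DESeq2 in edgeR, no filter on low counts, a filter of 1 CPM in 9 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1) with colony as a fixed or random term, edgeR with robust estimation, either lane alone, fits of 1 week or 1 colony alone, sums over weeks, and each colony or week left out. A log2 fold change of at least 1 was tried as an added condition. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.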

Results

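Gene expression was measured in polyps of 3 colonies of the coral Lophelia pertusa, a reef builder of cold and deep water, kept at pH 7.6 or pH 7.9. The design holds 1 library for each of the 3 colonies (1, 3 and 4), 3 sampling times (2, 4.5 and 8.5 weeks) and 2 pH levels. There were thus 9 libraries at each pH, 6 of each colony and 6 of each week, and 3 for each combination of pH and week. The lower pH is the treatment named in the title of the study, and pH 7.9 is the level it was compared with. Library totals ran from 18042191 to 25651213 counts, and 64559 to 69841 of 75743 transcripts had counts. Libraries at pH 7.6 held 22730679 ± 2426485 counts and those at pH 7.9 held 20718771 ± 1425793 (SD, n = 9). Over the 9 pairs of the same colony and week, the mean difference was 2011908 counts (two-sided exact permutation test over pairs, p = 0.0469). The totals were higher at pH 7.6 in 7 of the 9 pairs. The test counts the pairs as independent, though the 3 weeks of a colony are repeated samples. Levels of single transcripts are in CPM, counts scaled to library size. Transcript_36311 was the most abundant and took 1.81 to 5.91% of the counts of a library. Transcripts have numbers and no names in the file, so no gene functions are given.

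The libraries fell into 3 sets, which did not follow the colony labels. Set A held both week 2 libraries of colony 1, its pH 7.6 libraries of weeks 4.5 and 8.5, and the pH 7.9 libraries of colony 3 of weeks 4.5 and 8.5. Set B held the 3 pH 7.6 libraries of colony 3 and the pH 7.9 libraries of colony 1 of weeks 4.5 and 8.5. Set C held the 6 libraries of colony 4 and the week 2, pH 7.9 library of colony 3. Of the 18 libraries, 5 were therefore outside the set that held most libraries of their colony, and all 5 were at pH 7.9. The membership of the 18 libraries was the same with the other transcripts, with all transcripts, with transcripts above the median level, and with Pearson correlation and complete linkage. Principal component 1 (32.9% of the variance) and component 2 (23.7%) separated the same sets.

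**Figure D1:**
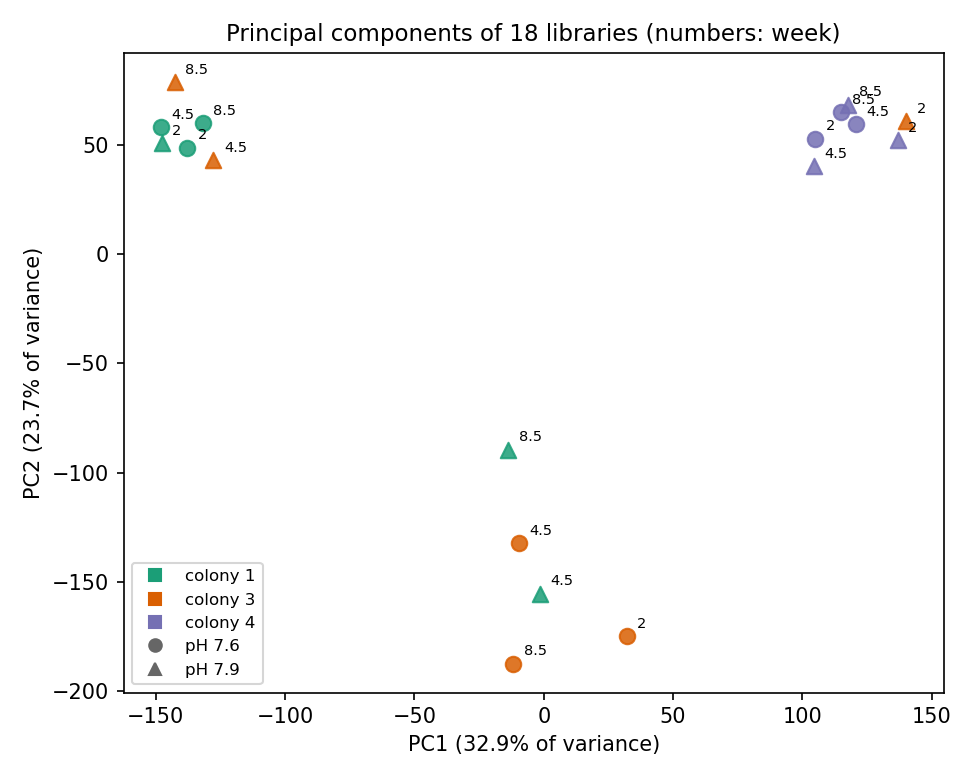
Principal components 1 and 2 of log2 CPM in the 18 libraries, in arbitrary units, with colour for the colony label, shape for pH and a number for the week. The pH 7.9 libraries of colony 3 lie in 2 places, with colony 1 at weeks 4.5 and 8.5 and with colony 4 at week 2, and the pH 7.9 libraries of colony 1 of weeks 4.5 and 8.5 lie with the pH 7.6 libraries of colony 3.

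Presence and absence of single transcripts divided the libraries in the same way. Among 28111 transcripts not used to form the sets, libraries of the same set differed by 0 to 7 transcripts with at least 100 counts in one library and 0 in the other (median 1, 46 pairs of libraries). Libraries of different sets differed by 8 to 73 (median 35, 107 pairs). The 19 pairs of the same colony label in different sets had a median of 32, and the 20 pairs of different colony labels in the same set had a median of 0.5. Spearman's correlation between libraries, across transcripts, had a median of 0.946 within sets and 0.864 between them. Each comparison below was made by the labels as given, and values with the library set in place of colony stand beside it where they differ by over 1.5 times. These were added after the data had been seen.

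**Figure D2:**
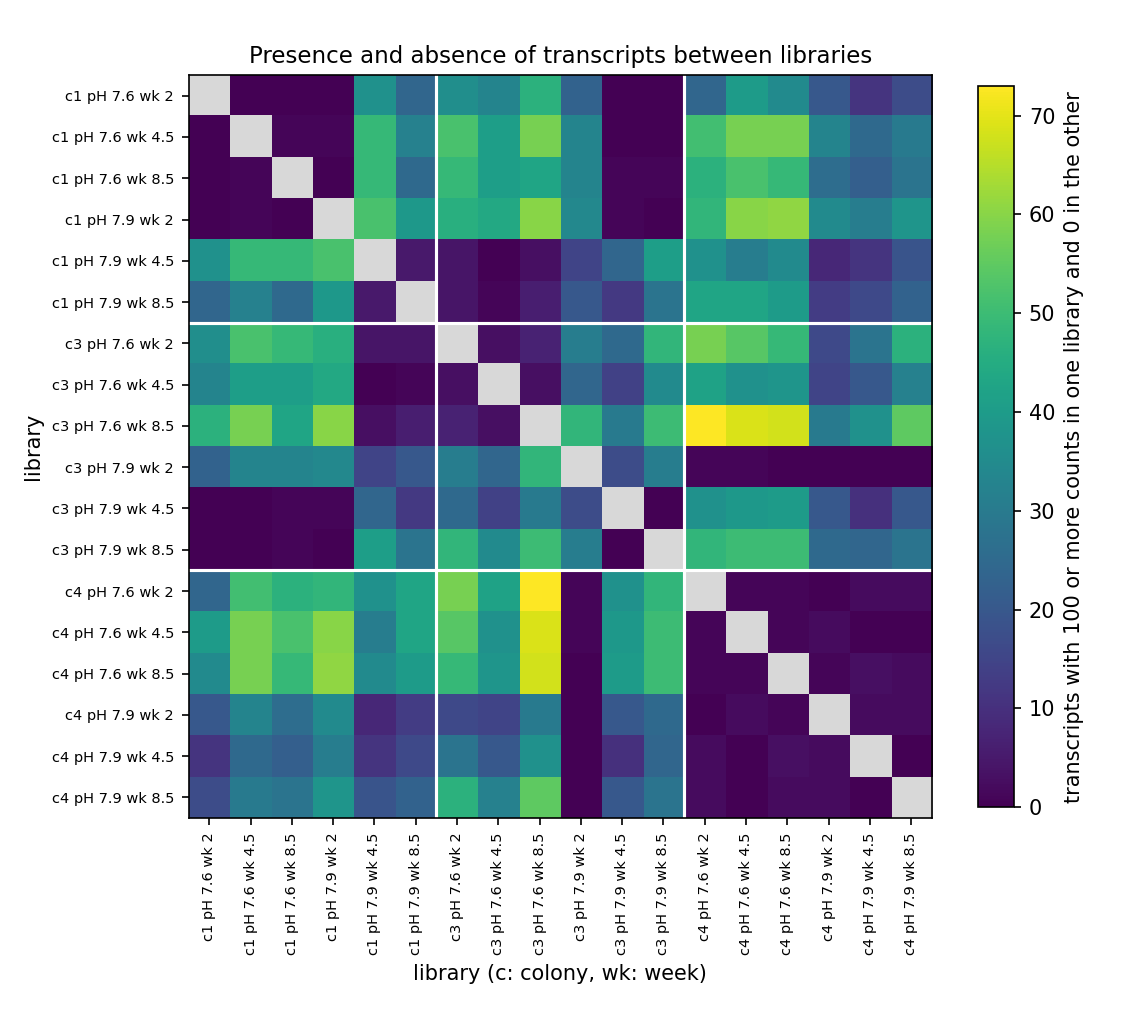
Number of transcripts with 100 or more counts in one library and 0 in the other, for each pair of the 18 libraries ordered by colony, pH and week, with white lines between colonies. Pairs of the same set lie between 0 and 7 and pairs of different sets between 8 and 73, and the blocks of colonies 1 and 3 are broken at pH 7.9.

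To find what the lower pH changed, the pH levels were compared over all weeks. At pH 7.6, 76 transcripts rose and 3 fell out of 56223 tested with edgeR's quasi-likelihood test, and 47 of these 79 changed in the same direction in all 9 pairs of libraries of the same colony and week. Transcript_2635 rose from 23 ± 20.7 CPM at pH 7.9 to 594 ± 714 CPM at pH 7.6 (SD, n = 9), a log2 fold change of 4.67 ± 0.48 (SE, edgeR adjusted p = 0.00184). Transcript_66519 rose from 2.71 ± 2.73 to 63.6 ± 63.3 CPM (SD, n = 9), by 4.61 ± 0.44 on the log2 scale (SE, edgeR adjusted p = 0.00152). Transcript_37171 fell from 43.4 ± 14.9 to 14.9 ± 7.92 CPM (SD, n = 9), with a log2 fold change of -1.62 ± 0.23 (SE, edgeR adjusted p = 0.0165). Transcript_54661 fell from 13.8 ± 3.75 to 7.85 ± 2.85 CPM (SD, n = 9), with a log2 fold change of -0.84 ± 0.15 (SE, edgeR adjusted p = 0.0471).

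The rule that named these transcripts required the same sign in all 9 pairs, which 47 of the 79 had, so their sign in each colony was fixed by selection and only sizes are compared. Transcript_2635 had log2 fold changes of 4.69, 4.36 and 4.94 in colonies 1, 3 and 4, and of 5.41, 4.27 and 4.68 in sets A, B and C. Transcript_66519 had 4.14, 4.36 and 5.12 in the colonies and 4.59, 4.57 and 4.82 in the sets. For Transcript_37171 the values were -1.12, -2.1 and -1.65 in the colonies and -1.33, -1.62 and -1.73 in the sets. For Transcript_54661 they were -0.76, -0.92 and -0.83 in the colonies and -1.19, -0.45 and -0.93 in the sets, and its adjusted p passed 0.05 in 13 of 19 alternative fits, with 0.051 under the size factors of DESeq2 in edgeR. With the library set in place of colony, 779 transcripts were called (504 higher and 275 lower at pH 7.6), among them 78 of the 79. DESeq2 called 955 (613 higher and 342 lower), also with 78 of the 79. The count was 0 when week 2, week 4.5, week 8.5 or colony 4 was left out, and 0 with counts summed over weeks. Without colony 1 it was 34 (26 higher and 8 lower, 18 of the 79 among them), and without colony 3 it was 409 (200 higher and 209 lower, with 54 of the 79). Without the 5 libraries outside their colony's main set it was 28 (22 higher and 6 lower), of which 7 were among the 79. The balance of 76 higher to 3 lower did not hold without colony 3, with DESeq2 or with the library set in place of colony.

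**Figure D3:**
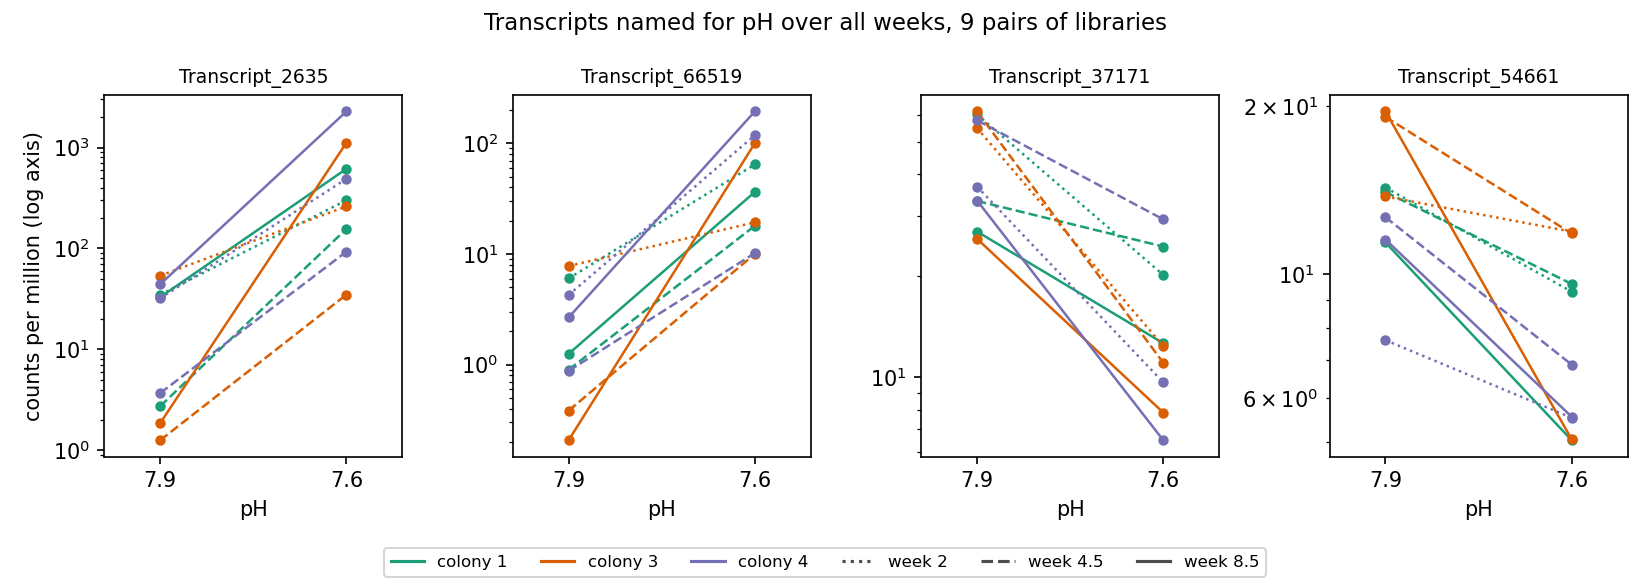
CPM on a log axis of the 4 transcripts named for pH over all weeks, in each library at pH 7.9 and pH 7.6, with a line joining the 2 libraries of the same colony and week, colour for colony and line style for week. All 9 lines rise from pH 7.9 to pH 7.6 for Transcript_2635 and Transcript_66519 and fall for Transcript_37171 and Transcript_54661.

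The comparison by week asked when the difference appeared. At week 8.5, 63 transcripts rose and 3 fell at pH 7.6, and all 66 changed in the same direction in the 3 colonies. Transcript_66519 rose from 1.38 ± 1.24 to 110 ± 79.7 CPM (SD, n = 3), with a log2 fold change of 6.47 ± 0.82 (SE, edgeR adjusted p = 0.0159). Transcript_9660 rose from 0.503 ± 0.361 to 38.3 ± 28.2 CPM (SD, n = 3), with a log2 fold change of 6.14 ± 1.07 (SE, edgeR adjusted p = 0.0476). Transcript_1136 fell from 20 ± 20.8 to 0.687 ± 0.696 CPM (SD, n = 3), with a log2 fold change of -4.84 ± 0.81 (SE, edgeR adjusted p = 0.0379). Transcript_30865 fell from 55.5 ± 22.9 to 6.56 ± 2.83 CPM (SD, n = 3), with a log2 fold change of -3.19 ± 0.56 (SE, edgeR adjusted p = 0.0481). At week 2 edgeR called 0 transcripts, with 3069 at an unadjusted p below 0.05, where DESeq2 called 78 and limma-voom 2. At week 4.5 edgeR called 0, with 1207 at an unadjusted p below 0.05, where DESeq2 called 13.

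A test of whether the pH effect differed between weeks called 0 transcripts in edgeR, with 1769 at an unadjusted p below 0.05, and 39 in DESeq2, so a response at week 8.5 alone was not shown by edgeR. At weeks 2, 4.5 and 8.5 the log2 fold changes of the 4 transcripts named for week 8.5 were 3.12, 4.24 and 6.47 for Transcript_66519, 2.8, 2.35 and 6.14 for Transcript_9660, 1.4, -3.14 and -4.84 for Transcript_1136, and -0.61, -1.31 and -3.19 for Transcript_30865. They were chosen for their size at week 8.5, and their adjusted p passed 0.05 in 5, 8, 7 and 6 of 15 alternative fits, in the same order. For Transcript_9660 it was 0.0532 with robust estimation in edgeR. The week 8.5 count was 826 with the library set in place of colony (560 higher and 266 lower), 828 with DESeq2 (599 higher and 229 lower), 1 without the 5 libraries outside their colony's main set, and 1, 4 and 0 without colony 1, 3 and 4. It was 0 when the 6 libraries of the week were fitted alone. The week 2 count was 2, and the count for the difference between weeks was 15, with the library set in place of colony.

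The colonies were next compared in their response, since the design holds genetically distinct colonies. In colony 3, 1685 transcripts were higher and 1855 lower at pH 7.6, and 3490 of these 3540 had the same direction at all 3 weeks. Transcript_72775 rose from 1.67 ± 1.03 to 141 ± 58.6 CPM (SD, n = 3), with a log2 fold change of 6.4 ± 1.33 (SE, edgeR adjusted p = 0.0161). Transcript_58032 rose from 0.784 ± 0.141 to 58.3 ± 14.6 CPM (SD, n = 3), with a log2 fold change of 6.27 ± 0.99 (SE, edgeR adjusted p = 0.00939). Transcript_19611 fell from 96 to 311 counts per library at pH 7.9 to 0 to 1 counts at pH 7.6 (edgeR adjusted p = 0.0157). Transcript_71768 fell from 107 to 211 counts to 0 to 1 counts (edgeR adjusted p = 0.0061). In colony 3 no library at pH 7.9 was in the set of the 3 libraries at pH 7.6. In colony 1 at weeks 4.5 and 8.5, where the pH 7.9 libraries lay in that set, these transcripts changed the opposite way. Transcript_72775 stood at 94.8 and 90.2 CPM at pH 7.9 against 0.634 and 1.01 at pH 7.6. For Transcript_58032 these were 47.6 and 29.7 against 0.55 and 0.876 CPM. Transcript_19611 had 4 and 0 counts at pH 7.9 against 311 and 231 at pH 7.6. Transcript_71768 had 5 and 83 against 129 and 108 counts.

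In colonies 1 and 4 edgeR called 0 transcripts each, with 6874 and 4332 at an unadjusted p below 0.05, where DESeq2 called 1506 and 153. Fitted to the 6 libraries of each colony alone, edgeR called 0 in colony 1, 1070 in colony 3 and 60 in colony 4 (40 higher and 20 lower). A test of whether the pH effect differed between colonies called 2123 transcripts, of which 1734 were among the 3540 of colony 3. Independent lists would share 134, though the 2 tests use the same libraries. The 3540 transcripts had the opposite sign in colony 1 at weeks 4.5 and 8.5 in 91.4% of cases, at week 2 of colony 1 in 43.4%, and in colony 4 in 37.8%. Without week 2, colony 1 had 5207 calls and colony 3 had 7016, and the difference between colonies 8108. Without week 4.5 and without week 8.5, colony 3 had 417 and 0 calls and the difference between colonies 0 each. Without the 5 libraries outside their colony's main set, colony 3 had no library at pH 7.9 and colony 1 only that of week 2. No count is therefore given for the difference between colonies in that fit.

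**Figure D4:**
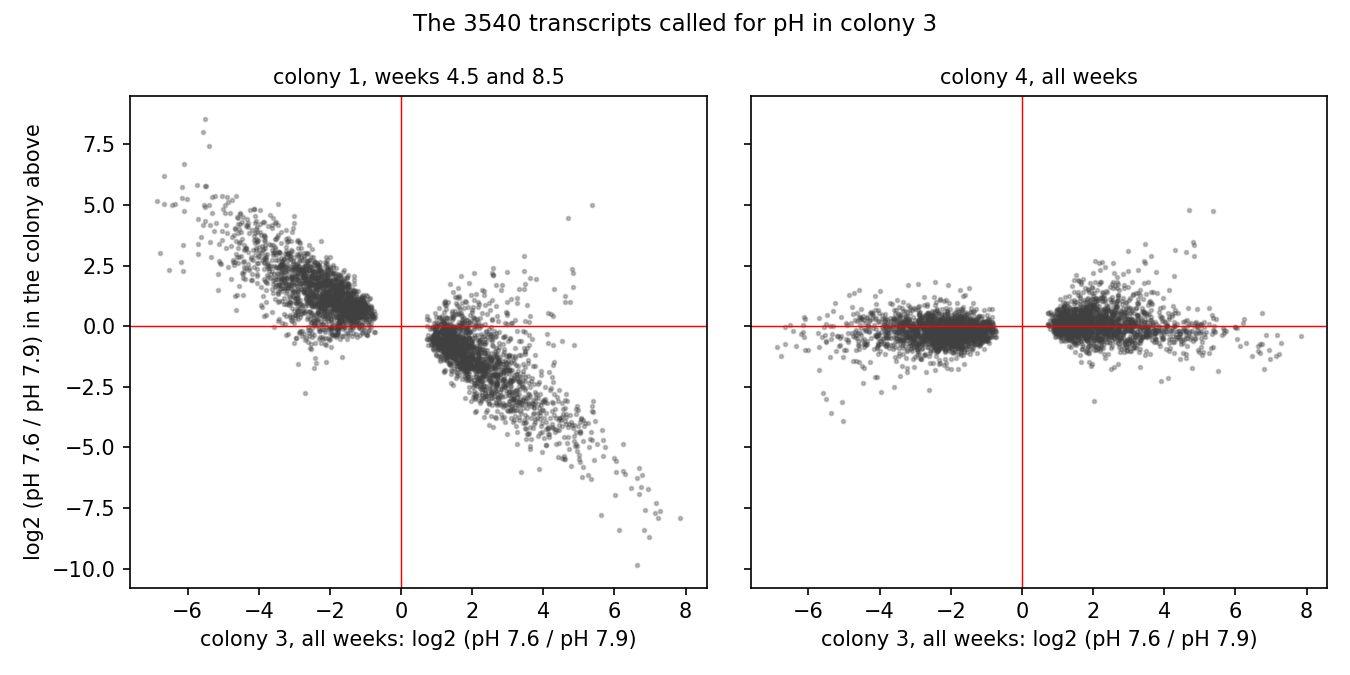
Log2 ratio of pH 7.6 to pH 7.9 for each of the 3540 transcripts called in colony 3, as the mean over the weeks of colony 3 (horizontal) against colony 1 at weeks 4.5 and 8.5 (left) and colony 4 at all weeks (right), with red lines at 0. The sign is opposite for 91.4% of the transcripts in the left panel and for 37.8% in the right panel.

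Within the sets, pH was compared with the second model and the set in place of the colony, also added after the data had been seen. In set C, with 3 libraries at pH 7.6 and 4 at pH 7.9, 17 transcripts were higher and 2 lower at pH 7.6. In set B, with 3 and 2 libraries, 0 were higher and 4 lower. All 3 libraries of set B at pH 7.6 were labelled colony 3 and both at pH 7.9 colony 1, so that by the labels these calls cannot be assigned to pH or to colony. In set A, the 3 libraries at pH 7.6 were labelled colony 1, and 2 of the 3 at pH 7.9 were labelled colony 3. Set A, with 3 libraries at each pH, gave 0 calls in edgeR, with 2245 transcripts at an unadjusted p below 0.05. The test of whether the pH effect differed between sets called 0 transcripts, with 2961 at an unadjusted p below 0.05. DESeq2 was not run by set. The common dispersion was 0.0944 with the set as a term in the first model, against 0.21 with colony. The sets were formed by the likeness of these same libraries, so a lower spread followed from how they were made. It does not show that the set is the better term.

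The colonies were compared by their labels as given, over all weeks and both pH. Against colony 1, 3009 transcripts were higher and 3709 lower in colony 4, and 6071 of these 6718 had the same direction in all 6 pairs of libraries of the same week and pH. Transcript_13039 was at 80.1 ± 25.5 CPM in colony 4 and 0.684 ± 1.16 in colony 1 (SD, n = 6), a log2 fold change of 7.51 ± 1.52 (SE, edgeR adjusted p = 0.00881). Transcript_59368 was at 70 ± 26 and 0.579 ± 0.59 CPM (SD, n = 6), a log2 fold change of 7.22 ± 1.34 (SE, edgeR adjusted p = 0.00614). Transcript_73092 was at 0.114 ± 0.0924 CPM in colony 4 and 29.7 ± 18.2 in colony 1 (SD, n = 6), a log2 fold change of -7.81 ± 0.98 (SE, edgeR adjusted p = 0.00341). Transcript_81058 was at 2.6 ± 2.77 and 228 ± 198 CPM (SD, n = 6), a log2 fold change of -7.14 ± 1.3 (SE, edgeR adjusted p = 0.0056).

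Against colony 3, 796 transcripts were higher and 1502 lower in colony 4, and 1401 of these 2298 had the same direction in all 6 pairs. Transcript_81418 was at 62.7 ± 18.1 CPM in colony 4 and 9.08 ± 21 in colony 3 (SD, n = 6), a log2 fold change of 5.63 ± 1.21 (SE, edgeR adjusted p = 0.0235). Transcript_3076 was at 63.8 ± 8.97 and 7.86 ± 16.7 CPM (SD, n = 6), a log2 fold change of 4.85 ± 1.2 (SE, edgeR adjusted p = 0.039). Transcript_2871 was at 0.101 ± 0.151 CPM in colony 4 and 15.1 ± 9.6 in colony 3 (SD, n = 6), a log2 fold change of -7.14 ± 1.04 (SE, edgeR adjusted p = 0.0112). Transcript_65832 was at 0.507 ± 0.888 and 38.5 ± 38 CPM (SD, n = 6), a log2 fold change of -6.61 ± 1.06 (SE, edgeR adjusted p = 0.0112). The 4 were closest to the level of colony 4 in the week 2, pH 7.9 library of colony 3, where Transcript_81418 stood at 52 CPM against 0.31 to 1.02 CPM in the other 5.

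Between colonies 3 and 1, edgeR, DESeq2 and limma-voom each called 0 transcripts, and 3470 had an unadjusted p below 0.05 in edgeR. Libraries of both labels were present in sets A and B. Without the 5 libraries outside their colony's main set, a fit added after the data had been seen, 5305 transcripts were higher and 4103 lower in colony 3 than in colony 1. The counts were then 5760 and 5084 for colony 4 against 1, and 4092 and 4421 for colony 4 against 3. That fit left out the libraries least like their colony, which lowers the spread within colonies, and kept colony 3 at pH 7.6 alone. Among the libraries at pH 7.6, all in their colony's main set, pairs of colonies 1 and 3 differed by 33 to 58 transcripts with at least 100 counts in one library and 0 in the other. Pairs of colonies 1 and 4 differed by 24 to 58 and pairs of colonies 3 and 4 by 37 to 73. The 0 calls between colonies 3 and 1 therefore do not show that these colonies were alike.

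The weeks were compared to follow time in the experimental system. At week 8.5, 97 transcripts were higher and 480 lower than at week 2, and 537 of these 577 had the same direction in all 6 pairs of libraries of the same colony and pH. Transcript_21174 rose from 61.3 ± 45.1 to 314 ± 56.4 CPM (SD, n = 6), with a log2 fold change of 2.63 ± 0.5 (SE, edgeR adjusted p = 0.0235). Transcript_21000 rose from 615 ± 489 to 2550 ± 661 CPM (SD, n = 6), with a log2 fold change of 2.32 ± 0.49 (SE, edgeR adjusted p = 0.0394). Transcript_55411 fell from 174 ± 76.9 to 13.8 ± 15.6 CPM (SD, n = 6), with a log2 fold change of -4.68 ± 0.81 (SE, edgeR adjusted p = 0.015). Transcript_12877 fell from 11.9 ± 6.15 to 0.84 ± 0.64 CPM (SD, n = 6), with a log2 fold change of -3.96 ± 0.79 (SE, edgeR adjusted p = 0.0286).

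From week 4.5 to week 8.5, 31 transcripts rose and 324 fell. Transcript_36998 rose from 1.01 ± 0.97 to 69.7 ± 63 CPM (SD, n = 6), with a log2 fold change of 5.6 ± 1.05 (SE, edgeR adjusted p = 0.03). Transcript_13988 rose from 0.847 ± 0.476 to 33.5 ± 33.8 CPM (SD, n = 6), with a log2 fold change of 4.11 ± 0.39 (SE, edgeR adjusted p = 0.00287). The 3 libraries at pH 7.6 carried most of this rise, as they stood at 56.9 to 68 CPM at week 8.5 and the 3 at pH 7.9 at 0.518 to 4.24 CPM. Transcript_55411 fell from 181 ± 204 to 13.8 ± 15.6 CPM (SD, n = 6), with a log2 fold change of -4.36 ± 0.78 (SE, edgeR adjusted p = 0.0264), and at week 8.5 stood at 1.75 to 3.17 CPM at pH 7.6 and 8.54 to 36 CPM at pH 7.9. Transcript_3610 fell from 9.11 ± 6.88 to 0.664 ± 1.09 CPM (SD, n = 6), with a log2 fold change of -4.58 ± 0.64 (SE, edgeR adjusted p = 0.0171).

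From week 2 to week 4.5, 3 transcripts rose and 21 fell. Transcript_3979 rose from 46.7 ± 14.9 to 140 ± 65.1 CPM (SD, n = 6), with a log2 fold change of 1.5 ± 0.21 (SE, edgeR adjusted p = 0.0283). Transcript_74958 rose from 18.8 ± 6.17 to 50.2 ± 23.7 CPM (SD, n = 6), with a log2 fold change of 1.36 ± 0.17 (SE, edgeR adjusted p = 0.0243). Transcript_13988 fell from 4.58 ± 2.88 to 0.847 ± 0.476 CPM (SD, n = 6), with a log2 fold change of -2.38 ± 0.37 (SE, edgeR adjusted p = 0.0444). Transcript_7689 fell from 27.6 ± 29.2 to 5.47 ± 3.12 CPM (SD, n = 6), with a log2 fold change of -2.12 ± 0.33 (SE, edgeR adjusted p = 0.0444).

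**Figure D5:**
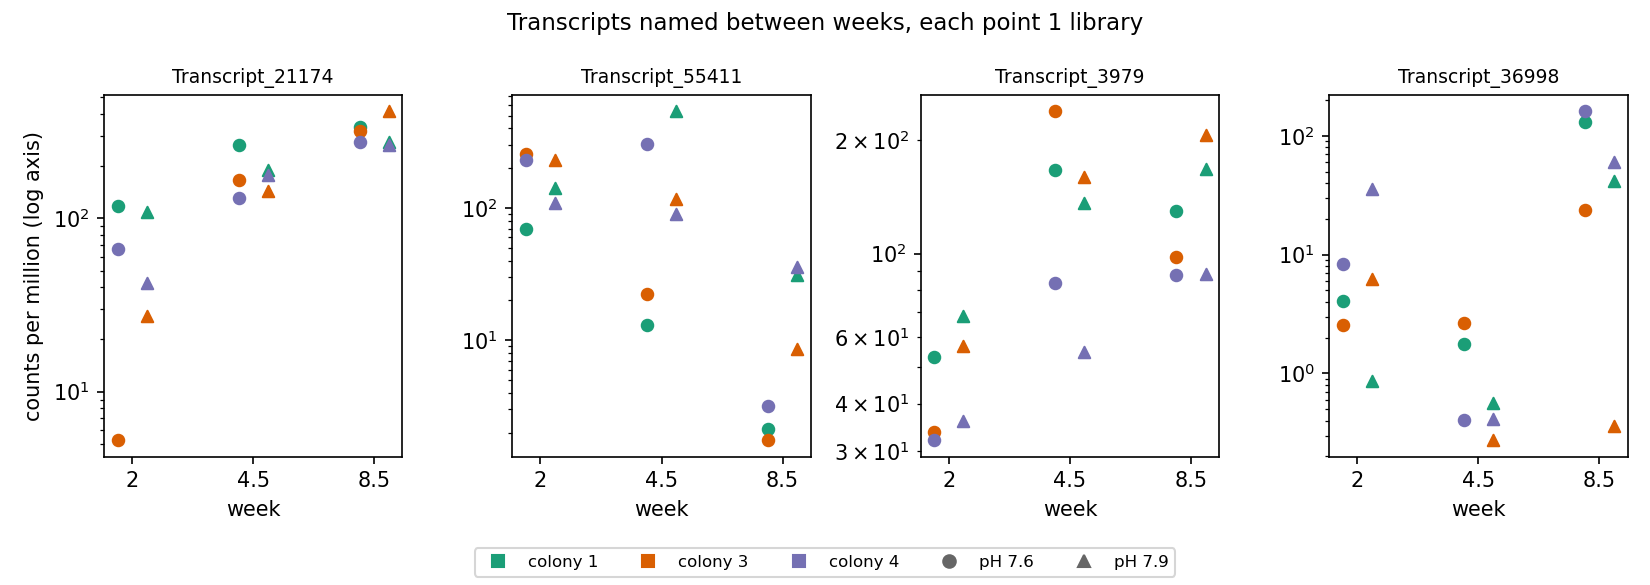
CPM on a log axis of 4 transcripts named between weeks, in each of the 6 libraries of weeks 2, 4.5 and 8.5, with colour for colony and shape for pH. Transcript_21174 stands at 263 to 414 CPM at week 8.5 against 5.24 to 118 CPM at week 2, and Transcript_55411 at 1.75 to 36 CPM against 69.7 to 256 CPM.

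The counts between weeks moved with the choice of block and with single colonies. With the library set in place of colony they were 2176 (612 higher and 1564 lower at week 8.5 than at week 2), 1517 (216 and 1301, week 8.5 against 4.5) and 471 (223 and 248, week 4.5 against 2), and without the replicate block the last was 15. Without colony 1 they were 1, 0 and 0, without colony 3 they were 168, 15 and 175, and without colony 4 they were 25, 0 and 0. Without the 5 libraries outside their colony's main set they were 207, 4 and 1. For week 4.5 against 2, DESeq2 called 411 higher and 578 lower, and without colony 3 there were 110 higher and 65 lower, so the balance of 3 to 21 did not hold. The ratio of the counts of the 2 lanes also differed between weeks. It was 0.468 to 4.48 at week 2, 0.999 to 1.006 at week 4.5 and 1.007 to 1.012 at week 8.5. No value of week 4.5 overlapped with week 8.5. The range of week 2 included both, but no single library of week 2 lay within either, with the nearest at 0.837 and 1.065. The labels give no sequencing run.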

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

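The tests of mislabelled libraries, of fragments of more than 1 genotype, of a pH effect alike in all colonies and of the sequencing run were chosen after the result was seen, as was the fit with the library set in place of colony. The test of the colony 3 transcripts in colony 1 and the counts over other splits of the libraries were fixed before their results were seen, though the library sets themselves were known by then.

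The pattern that bears on most comparisons is that 5 libraries, all of the 9 at pH 7.9 and none of the 9 at pH 7.6, sat with libraries of another colony. The pattern itself, being unequal between colonies, argues against a pH effect alike in all colonies as the whole origin. The 2 pH levels of the same week differed by 0 to 2 transcripts on in one library and off in the other in colony 4, and by 14 to 50 in colony 3. In colony 1 they differed by 0, 49 and 25 at weeks 2, 4.5 and 8.5. These numbers restate the pattern, since all libraries of colony 4 were in set C and each pair of colony 3 spanned 2 sets. A pH effect that differs between colonies and weeks would have to give the 5 libraries the on and off transcripts of another colony. At weeks 4.5 and 8.5, those of colony 1 differed by means of 2.33 and 3.67 from the pH 7.6 libraries of colony 3. From those of their own colony it was 45 and 27. At these weeks those of colony 3 differed by 0.333 each from colony 1, and at week 2 by 0.667 from colony 4. From their own it was 23, 44.3 and 34.3. Pairs of the same colony and set differed by 0 to 7. The values argue against such an effect as the whole origin. Mislabelled libraries and fragments of more than 1 genotype under a colony label both stay open and cannot be told apart, since no genotypes were measured here. All 5 libraries were closer, in transcripts on in one library and off in the other, to the pH 7.6 libraries of another colony. As all pH 7.6 libraries lie in their colony's main set, that they were closer restates the pattern and does not separate these explanations. The two-sided Fisher's exact p of 0.0294 (5 of 9 against 0 of 9) decides nothing either, since it restates the pattern and counts as independent the libraries of colonies 1 and 3 that are out of place together at weeks 4.5 and 8.5.

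The pH effect differed between colonies in 2123 transcripts by a test of the difference itself, with 3540 called in colony 3 and 0 in colonies 1 and 4. If the library sets and not pH were behind these calls, the transcripts of colony 3 should change the opposite way in colony 1 at weeks 4.5 and 8.5, where the sets lie the other way round across pH, and 91.4% did. A pH response confined to colony 3 required 40 to 60%, so the 91.4% argues against that narrower explanation only. The sets were known beforehand, and transcripts that differ between sets A and B reverse there whatever placed the libraries in the sets. Opposite pH responses of colonies 1 and 3 would give the same share. The test therefore cannot separate the library sets from a pH effect that differs between colonies. At week 2, where both libraries of colony 1 were in set A, the share was 43.4%. Of 31 splits of the libraries that exchange the pH labels within pairs of the same colony and week, 2 gave as many transcripts, with 2692 as the highest other count, so chance was not excluded. The split with 2692 exchanged all 3 pairs of colony 3, those of colony 1 at weeks 4.5 and 8.5, and that of colony 4 at week 4.5. It thus exchanged every pair that joins libraries of different sets. The sets were parted as by the labels, with the sign reversed, which points to a structure of the libraries. Such a split is no test of chance, so the share decides nothing.

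The transcripts called between weeks may carry a difference between sequencing runs. The lowest lane ratio at week 8.5 was 1.007, above the highest at week 4.5, so for these 2 weeks time and run cannot be told apart, since the labels give no run. The range of week 2 (0.468 to 4.48) included both others, but no single library of week 2 lay within either. The nearest were at 0.837 and 1.065, so time and run cannot be told apart for week 2 either. Chance was excluded for all 3 comparisons of weeks, but only for splits that exchange the weeks within each colony and pH on its own. Week 4.5 against 2 had 24 calls against 2 in the highest other split, week 8.5 against 2 had 577 against 5, and week 8.5 against 4.5 had 355 against 1, with 1 of 21 splits as large in each. That share is the smallest that 21 splits allow, and no allowance was made for the number of such tests. The splits count the 2 pH of a colony as independent, so chance at the level of colonies was not excluded. A response to time in the system remains open and untested.

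Where more splits exist, 30 or 20 besides the real one were drawn with a fixed seed. For pH over all weeks the labels gave 79 calls, against 27 in the highest of the other splits (1 of 31 as large). The splits exchange each pair of the same colony and week on its own. All pairs of colony 3, and those of colony 1 at weeks 4.5 and 8.5, join libraries of different sets. Exchanging some of them shifts the sets between the pH groups, which the labels nearly balance. Sets A, B and C held 3, 3 and 3 libraries at pH 7.6 and 3, 2 and 4 at pH 7.9. The real count was therefore often set against splits of unlike structure, which cannot exclude chance. The splits also count the 3 weeks of a colony as independent, though these are repeated samples. Chance at the level of colonies was not excluded either. With counts summed over weeks there were 0 calls. With the library set in place of colony the counts were 779 and 71 (1 of 21 as large). Chance was there excluded only for splits that exchange single libraries within sets and across the pairs of colony and week. The sets came from the same data, and in sets A and B pH runs largely or fully with the colony label. For the difference of the pH effect between weeks, all 31 splits gave at least the 0 calls found, with 5 at most. At single weeks and in single colonies there are 10 splits, too few for a share under 0.05. The real and the highest other count were 0 and 2306 at week 2, 0 and 0 at week 4.5, 66 and 0 at week 8.5, 0 and 0 in colony 1, 3540 and 1 in colony 3, and 0 and 0 in colony 4, with as many transcripts in 10, 10, 1, 10, 1 and 10 splits. These splits also move libraries across the pairs of the same colony and week. Only 4 of the 10, the real one included, keep 1 library of each pH in every pair, and among those the highest other count was 1 in colony 3 and 0 at each week and in colonies 1 and 4. The week 2 split with 2306 exchanged the pH 7.9 library of colony 1 and the pH 7.6 library of colony 3, so that it set both libraries of colony 1 against both of colony 3, which points to a structure of the libraries. Colony 4 against 1 had 6718 calls against 544 (1 of 21). Chance was excluded there only for splits of these libraries, which are repeated samples of 1 colony each. Colony 4 against 3 had 2298 against 2328 (2 of 21), so chance was not excluded. The split with 2328 exchanged the week 2, pH 7.9 libraries of colonies 3 and 4, which both lie in set C. Colony 3 against 1 had 0 calls in all 21 splits.

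In 14 of 86 groups of 6 or 9 libraries, the gap of 1 library to the nearest other was large against the range of the group (Dixon's 95% limit). For transcripts the gap was taken on a log2 scale, while CPM are printed below. Chance gives about 1 in 20 in independent groups. These groups share libraries and hold transcripts named for their differences, so that rate is only a rough guide. The week 2, pH 7.9 library of colony 3 stood apart from the other 5 of its colony in Transcript_81418 (52.0 CPM against 0.31 to 1.02), Transcript_3076 (41.9 against 0.621 to 1.48), Transcript_2871 (0.0502 against 9.78 to 27.4) and Transcript_65832 (0.352 against 16.7 to 110). The week 2, pH 7.6 library of colony 4 had a lane ratio of 4.48, the highest in its colony, its week and its pH, and its 10 most abundant transcripts took 6.26% of counts against 10.9 to 11.9% in the rest of the colony. The lane ratio was lowest at pH 7.9 in the week 2 library of colony 1, at 0.468, and highest at week 4.5 in the pH 7.6 library of colony 4, at 1.006. The week 8.5, pH 7.9 library of colony 1 had 69841 transcripts with counts, against 66790 to 67857 in the rest of its colony. Transcript_81058 was at 8.21 CPM in the week 4.5, pH 7.9 library of colony 4, against at most 2.05 in the other 5. Transcript_12877 was at 2.04 CPM in the week 2, pH 7.6 library of colony 3, against at least 8.88 in the other libraries of week 2. Transcript_36998 was at 0.362 CPM in the week 8.5, pH 7.9 library of colony 3, against at least 23.8 in the other libraries of week 8.5.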

How the results depend on the processing

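Of the settings below, the library set in place of colony, the fits without 5 libraries and the fits of pH over all weeks without 1 week were chosen after the data had been seen. Counts of called transcripts stayed within 1.5 times with size factors of DESeq2 in edgeR, without the low-count filter, with robust estimation, with lane 1 alone and with an added log2 fold change of at least 1, for each comparison tested under them. Of 422 single fits of the 32 named values, 113 lost an adjusted p below 0.05. The 8 values that kept it throughout were those of the colony comparisons, which had 8 or 9 settings and only 1 that left out libraries, and each of the others lost it at least once. No direction reversed, which the rule for naming made nearly certain and which says nothing about the called lists. The cause of the changes below was not tested, except where fewer libraries were fitted.

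For pH over all weeks (79 calls) the count was 121 with at least 1 CPM in 9 libraries, 955 with DESeq2 (613 higher and 342 lower), 779 with the library set in place of colony, 0 with counts summed over weeks and colony as replicate block, and 28 without the 5 libraries outside their colony's main set. Leaving out 1 colony gave 0 to 409 (without colony 3, 200 higher and 209 lower) and leaving out 1 week gave 0 each. At week 8.5 (66 calls) it was 0 for the 6 libraries of that week alone and 0 to 4 without 1 colony. It was 828 with DESeq2 (599 higher and 229 lower) and 826 with the library set (560 and 266). At week 2 (0 calls) it was 78 with DESeq2, 2 with the library set, 2 with limma-voom and 1 without the 5 libraries. At week 4.5 (0 calls) it was 13 with DESeq2. For the difference between weeks (0 calls) it was 39 with DESeq2 and 15 with the library set.

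In colony 1 (0 calls) the count was 1506 with DESeq2, 1 with limma-voom, and 0 to 5207 without 1 week. In colony 3 (3540 calls) it was 1070 for the 6 libraries of that colony alone, 7143 with DESeq2, and 0 to 7016 without 1 week. In colony 4 (0 calls) it was 60 for its 6 libraries alone, 153 with DESeq2 and 2 without the 5 libraries. For the difference between colonies (2123 calls) it was 1266 with at least 1 CPM in 9 libraries, 5919 with DESeq2, and 0 to 8108 without 1 week. DESeq2 called 10974 between colonies 4 and 1 (6718 calls) and 6048 between colonies 4 and 3 (2298 calls). Without the 5 libraries these were 10844 and 8513, and colony 3 against 1 (0 calls) gave 9408.

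Between weeks 4.5 and 2 (24 calls) the count was 989 with DESeq2 (411 higher and 578 lower), 15 with lane 2 alone, 471 with the library set (223 and 248), 39 with limma-voom, 15 with no replicate block, 1 without the 5 libraries, and 0 to 175 without 1 colony (110 and 65 without colony 3). Between weeks 8.5 and 2 (577 calls) it was 1974 with DESeq2, 2176 with the library set, 207 without the 5 libraries and 1 to 168 without 1 colony. Between weeks 8.5 and 4.5 (355 calls) it was 1245 with DESeq2, 1517 with the library set, 4 without the 5 libraries and 0 to 15 without 1 colony. Removing the block moved no other count by over 1.5 times.

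The alternatives planned for gene lists were not run, because the transcripts could not be matched to gene names, and pH in colony 3 gave no value without the 5 libraries. With 18042191 to 25651213 counts per library, depth limits transcripts of few counts, and the spread between libraries limits the others. In simulated data for 54900 transcripts with 100 changed 2-fold, 33 were called for pH over all weeks and 0 to 2 at a single week, so that changes of that size at a single week were mostly not detectable with 3 libraries per group.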

Other observations

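A few transcripts differed between the lanes of the same library. This occurred in 3 libraries, all of week 2, and in 15 transcripts, of which 9 differed in at least 2 libraries. Transcript_78213 had 116 counts in lane 1 and 1133 in lane 2 of the week 2, pH 7.6 library of colony 4, whose lanes held 16433031 and 3664793 counts in total, and 420 and 67 counts in the lanes of the week 2, pH 7.6 library of colony 3. It had 25 to 2097 counts in the libraries of week 2 and at most 10 in any library of the later weeks. Transcript_43719 had 71 and 712 counts in the lanes of the same library of colony 4, and 21 to 1403 counts at week 2 against at most 10 later. Both were chosen after their values were seen.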
